A study of Mus musculus with 8 samples.

How the data were processed

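RNA sequencing of hearts from C57BL/6 mouse embryos at embryonic day 9.5 gave 8 libraries, 4 labelled female and 4 labelled male. Per the labels' protocols, the sex of each embryo was read by genotyping Sry, the Y-linked testis-determining gene, in tissue other than the heart, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The labels do not say whether a library held the heart of a single embryo or a pool, nor whether embryos shared a litter, so p-values measure the spread between these libraries.

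The deposited counts per gene are whole numbers, in 1 table per library, and have not been normalized. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used with the mouse genome build GRCm38 (mm10). The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The labels name no kit that marks strand. Reads of a gene and of an antisense gene over it, such as Xist and Tsix, may therefore not be told apart. Each table lists 49315 genes. A table of raw counts for the whole series holds the same values in every cell and gave no separate result. A further deposited table holds a normalized signal: the authors divided the counts by 1 factor per library and list the 16460 genes with a total above 80 counts, as tested on the values with a relative tolerance of 1e-06. It was used only as an alternative. Symbols were found for 48970 gene identifiers. Of the 49056 identifiers also present in GENCODE M21, 91.4% had the same position there; the positions printed are those of the deposited tables, on GRCm38.

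Total counts ranged from 20105913 to 51134291 per library. Every pair of replicates differed by more than sampling noise, with a chi-square per gene of 7.93 to 192, so no library was counted as a repeat of another.

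Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM factors, robust quasi-likelihood test, 2-sided) for the contrast male minus female, with no covariate and all 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over the 16377 genes tested, and genes with an adjusted p below 0.05 were called. CPM values were scaled with the TMM factors, and errors of log2 fold changes are standard errors from the same fit. Gene lists for the heart, neighbouring cell types, blood, the sex chromosomes and general processes were fixed before the data were examined. Of the 33 lists, 32 had at least 5 tested genes and were tested with camera of limma 3.58.1 with a preset correlation of 0.01; chromosomes with at least 10 tested genes were tested in the same way. Camera with an estimated correlation and fry were alternatives. Sums of X-linked genes and their Y-linked partners, the share of counts on chromosome X and the share in erythroid genes were compared by exact 2-sided permutation tests over the 70 ways of dividing 8 libraries into 4 and 4, whose smallest possible p is 0.0286. Permutation tests were run in Python 3.11.15 with numpy 2.4.6. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the whole group; floors cover counting error only.

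The genes to name were set by a rule before the data were examined: every tested member of the Y-linked list and of the list of genes that escape X inactivation; of the called autosomal genes without predicted names, up to 12 in each direction, or, where fewer than 5 passed, the 5 with the smallest p in that direction; up to 6 further called X-linked genes; and, of each list described, its called members and the 2 members with the highest mean CPM. Lists given only by counts or library means have no members named, and 1 gene that the rule takes is not reported here. The members of the 6 pairs of X-linked and Y-linked partners were also fixed before the data were examined. Other genes named outside this rule are marked as chosen after their values were seen.

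The fit was tested on simulated counts drawn from the means and library sizes of these libraries, with each gene drawn independently. For the contrast male minus female over 16073 simulated genes, with 200 changed, it called 20.9% of the genes changed 1.5-fold, 67.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 5 false calls. With no gene changed it made 0 calls.

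Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no filter on low counts, a filter at 1 CPM in 4 libraries, an adjusted p below 0.01, a fold of at least 1.5, a fit that was not robust, the replicate number as a block, an erythroid covariate, 1 surrogate variable from sva 3.50.0, removal of chromosomes X and Y, limma on log2 of the authors' normalized signal plus 1, and leaving out each library in turn. Chosen after seeing the data were the fits without Female replicate 1 and Male replicate 2 together, with the mean of the foregut list as a covariate, with the length trend of each library as a covariate, and on the genes of the normalized table. The length trend is the rank correlation across genes of a library's deviation from the mean of all libraries with gene length.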

Results

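The study profiled messenger RNA of the mouse embryonic heart at embryonic day 9.5, when the heart is a looped tube that has begun to beat, and asked how male and female hearts of the C57BL/6 strain differ. There were 4 female and 4 male libraries. Total counts were 37157141, 50195447, 20105913 and 51134291 in Female replicates 1 to 4, and 28127586, 39773169, 21778953 and 29584171 in Male replicates 1 to 4. The mitochondrial share of counts ranged from 0.707% in Male replicate 2 to 1.72% in Female replicate 4. The first principal component of log2 CPM held 54.6% of the variance and set Male replicate 2 (71.6) apart from the other 7 libraries, which lay between -45.0 and 21.6. The sexes separated on the second component, with 13.8% of the variance. All tested genes entered, Xist and the Y-linked genes included, and components without chromosomes X and Y were not computed.

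Hearts of the 2 sexes were told apart by Xist and by genes of chromosome Y. Of 16377 genes tested, 6 differed, 5 of them higher in males and 1 higher in females. Xist, the noncoding RNA that coats and silences the inactive X chromosome (chromosome X, 103460375 to 103483217), stood at 248 ± 21.6 CPM in females and 0.443 ± 0.126 CPM in males (SD, n = 4 each), a log2 fold change of -9.09 ± 0.18 (SE, adjusted p = 1.65e-08, edgeR). Eif2s3y, a subunit of the translation initiation factor eIF2 (chromosome Y, 1010543 to 1028847), reached 62.8 ± 4.53 CPM in males (SD, n = 4), with a log2 fold change of 9.18 ± 0.20 (SE, adjusted p = 1.93e-08). The RNA helicase Ddx3y (chromosome Y, 1260771 to 1286629) reached 47.7 ± 19.8 CPM in males, with a log2 fold change of 8.84 ± 0.45. The histone demethylase Kdm5d (chromosome Y, 897788 to 956786) reached 14.5 ± 4.14 CPM, with a log2 fold change of 8.45 ± 0.42. Uty, the Y-linked relative of the histone demethylase Kdm6a (chromosome Y, 1096861 to 1245759), reached 11.4 ± 1.17 CPM, with a log2 fold change of 8.13 ± 0.31. Female libraries held 0 to 7 counts of each of these 4 genes, and male libraries held 228 to 2629. The predicted gene Gm29650 (chromosome Y, 1048393 to 1049134), named after its values were seen, had 0 counts in all female libraries and 101 to 175 in male libraries, at least 256-fold higher in males against a floor of 3 counts over the female group (adjusted p = 0.000376, edgeR). All 8 libraries carried the pattern of their labelled sex. With the replicate number as a block the adjusted p of Gm29650 was 0.15, the highest of its alternatives, which ran down to 7.74e-18.

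**Figure D1:**
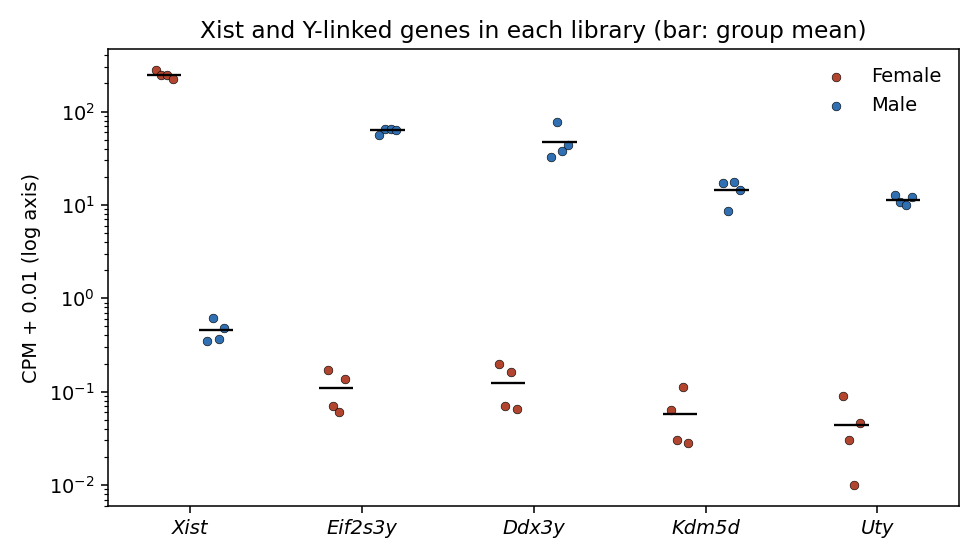
Xist and the 4 Y-linked genes of the fixed list that were tested, in each library, on a log axis of CPM plus 0.01; red points are female and blue points male libraries, and bars are group means. The female points of Xist (mean 248 CPM) and the male points of the Y-linked genes (means 11.4 to 62.8 CPM) lie apart from those of the other sex.

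Genes that escape X inactivation are transcribed from both X chromosomes of a female cell. The fixed list for them, which also counts Xist, the RNA of the inactive X, was lower in males as a group. Of the 15 tested members of the list, 14 had lower values in males, with a median log2 fold change of -0.34. Over all genes tested, 1 of the 15 was called (Xist), and adjusted over the list alone 8 were called. Kdm6a, the X-linked histone H3 lysine demethylase, stood at 27.5 ± 1.47 CPM in females and 16.4 ± 1.79 CPM in males (SD, n = 4 each), a log2 fold change of -0.75 ± 0.10 (SE) with an adjusted p of 0.0719 over all genes in edgeR and 0.000231 over the list alone. Eif2s3x had a log2 fold change of -0.63 ± 0.14, Jpx, a noncoding activator of Xist, -0.58 ± 0.15, 5530601H04Rik -0.44 ± 0.15, Pbdc1 -0.43 ± 0.09, Kdm5c -0.36 ± 0.12 and Ddx3x -0.34 ± 0.09 (SE), and each passed over the list alone but not over all genes. Mid1 (-0.24 ± 0.20), Ftx (-0.22 ± 0.26), Utp14a (-0.16 ± 0.08), Eif1ax (-0.04 ± 0.12), Shroom4 (-0.01 ± 0.13) and 1810030O07Rik (-0.01 ± 0.12) did not pass, nor did Car5b, the member with a higher value in males (0.84 ± 0.42). Of these, Mid1 was at -0.13 without Female replicate 4, -0.38 without Male replicate 1 and -0.12 without Male replicate 2. Ftx was at -0.12 without Female replicate 1 and -0.0076 without Male replicate 2, and Car5b at 0.45 without Male replicate 2. The set test of the list gave an adjusted p of 2e-59 with a preset correlation, and the call held with an estimated correlation (adjusted p = 0.000253). It also held without Xist, when 13 of 14 members were lower in males. The adjusted p was then 1.39e-11 with the preset correlation and 0.0208 with an estimated correlation. Kdm6a passed over all genes with DESeq2 (adjusted p = 1.49e-07) and without Male replicate 2 (adjusted p = 0.0229), so that 2 X-linked genes were then called. It also passed with no filter (adjusted p = 0.0388), the 1 CPM filter (0.0482) and 1 surrogate variable (4.07e-06). The foregut (0.00506) and length (0.0034) covariates, chosen after seeing the data, gave the same call. Kdm6a did not pass in the other alternatives, and over all of them its adjusted p ran from 1.49e-07 to 0.9998.

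**Figure D2:**
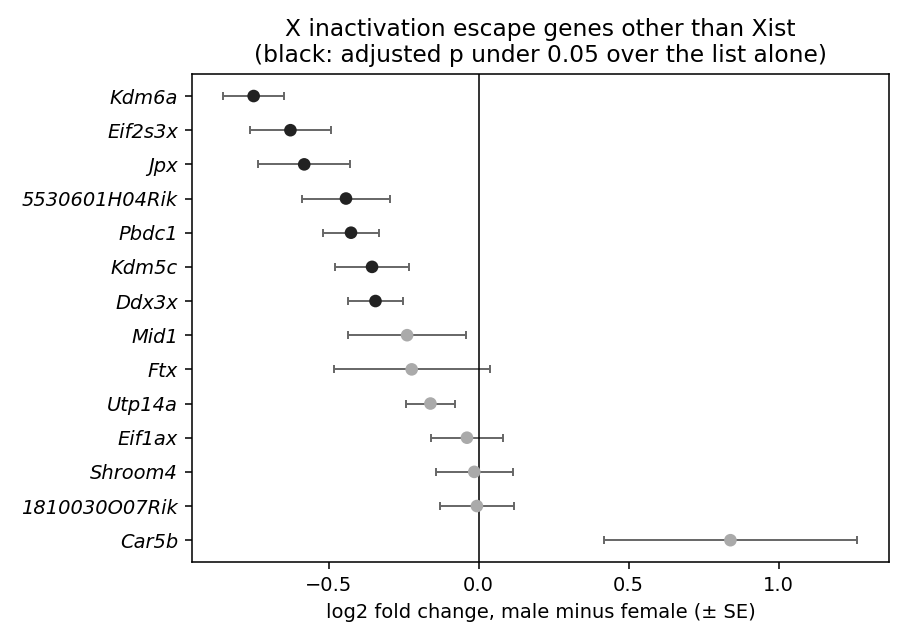
Log2 fold change, male minus female, of the 14 tested escape genes other than Xist, with bars of 1 SE; black points have an adjusted p below 0.05 over the list alone. The values run from -0.75 for Kdm6a to 0.84 for Car5b, and 13 of 14 lie below 0.

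Several of these escape genes have a partner on chromosome Y, and the summed CPM of both copies was compared. CPM is not corrected for gene length, so the sums and the shares of the Y copies do not measure numbers of transcripts. For Kdm6a and Uty the sum was 27.5 ± 1.49 CPM in females and 27.8 ± 2.62 CPM in males (SD, n = 4 each), with Uty giving 41.1% of the male sum. For Eif2s3x and Eif2s3y it was 70.3 ± 7.97 CPM in females and 108 ± 11.3 CPM in males, 1.54 times the female value (exact permutation p = 0.0286, the smallest the test can give, adjusted p = 0.171 over the 6 pairs), with Eif2s3y giving 58.0% of the male sum. The sum of Ddx3x and Ddx3y was 361 ± 27.7 CPM in females and 332 ± 26.1 CPM in males (exact permutation p = 0.2), and that of Kdm5c and Kdm5d was 92.0 ± 11.3 and 86.4 ± 13.4 CPM (exact permutation p = 0.571). For Usp9x with Usp9y and for Zfx with Zfy1, the Y copies had 3 and 2 counts over the male libraries, and the sums were 25.5 ± 12.7 against 24.1 ± 11.1 CPM and 27.8 ± 4.49 against 25.2 ± 4.59 CPM. None of the 6 sums passed after adjustment. A pair alone at the smallest p cannot pass over 6 pairs. Partners are similar in sequence, and how reads that fit both copies were counted is not given in the sources used here. The 4 expressed Y copies had 6 to 17 counts over the female libraries, and the source of these counts was not tested.

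**Figure D3:**
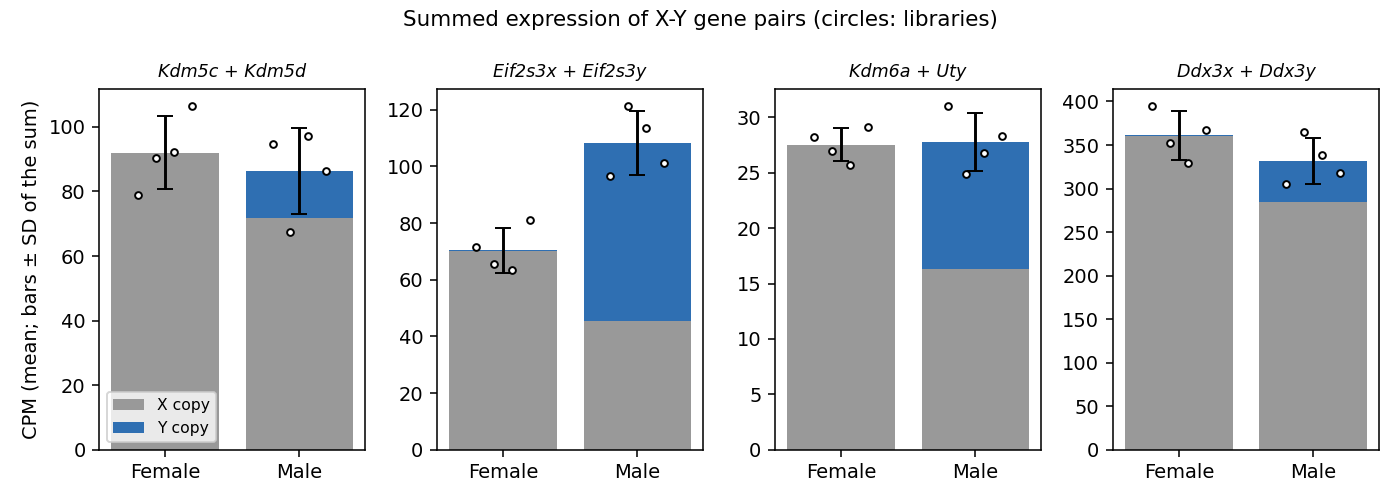
Mean CPM of the X copy (grey) and the Y copy (blue) of 4 gene pairs in female and male libraries, with the sum in each library as circles and bars of 1 SD of the sum, n = 4 each. The male sum is 1.54 times the female sum for Eif2s3x and Eif2s3y, and 1.01 times for Kdm6a and Uty.

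Chromosome X as a set did not pass the test for a shift in 1 direction. Of 542 X-linked genes tested, 306 had a lower value in males and 1 was called, against 0 of 15793 autosomal genes (Fisher's exact p = 0.0332, 2-sided), a difference that rests on Xist. Adjusted over the 542 genes alone 2 were called, Xist and Kdm6a (adjusted p = 0.00833). The median log2 fold change of X-linked genes was -0.03. It was -0.021 without Female replicate 1, -0.0025 without Female replicate 4 and -0.014 without Male replicate 2. Counts on chromosome X made up 2.75% ± 0.07 of the total in females and 2.62% ± 0.11 in males (SD, n = 4 each, exact permutation p = 0.0857), a difference of -0.13 percentage points that was -0.076 without Male replicate 2. Of 21 chromosomes tested as sets, none passed. The X set was lowest by p, with an unadjusted p of 0.00639 and an adjusted p of 0.134, and an adjusted p of 0.733 with an estimated correlation. It passed without Female replicate 3 (adjusted p = 0.0433), and its adjusted p over all alternatives ran from 0.0433 to 0.9959. With an estimated correlation, and with fry for a shift in 1 direction, 0 chromosomes passed. In fry's mixed test, which counts changes in either direction, chromosome X passed (adjusted p = 0.00515); without Xist, a test chosen after seeing the data, it did not (adjusted p = 0.609).

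No autosomal gene was called. Of 15793 autosomal genes, 340 had an unadjusted p below 0.05 in edgeR, and limma-voom on the same genes called 0 (369). Both counts lie under a share of 0.05, which chance alone gives on average where no gene differs. DESeq2, which tested 29917 genes over all chromosomes without that filter, called 0 autosomal genes (548 with an unadjusted p below 0.05). Without Female replicate 1 and Male replicate 2, a choice made after seeing the data, 0 autosomal genes were called (369 with an unadjusted p below 0.05). The 5 genes with the smallest p and higher values in males, none of which passed (adjusted p = 0.9995 for each), were the basement membrane proteoglycan Hspg2 (310 ± 33.0 CPM in females and 447 ± 54.5 CPM in males, SD, n = 4 each), the giant sarcomere protein Ttn (637 ± 158 and 1194 ± 231 CPM), Ankrd29 (7.37 ± 0.55 and 10.4 ± 1.26 CPM), the myosin heavy chain Myh7b (102 ± 3.99 and 136 ± 16.1 CPM) and the hyaluronan receptor Lyve1 (2.14 ± 0.24 and 3.45 ± 0.68 CPM). The 5 with higher values in females were Plac8 (16.5 ± 2.98 and 10.7 ± 0.94 CPM), Rprm (3.12 ± 0.32 and 2.02 ± 0.39 CPM), Moxd1 (0.872 ± 0.395 and 0.355 ± 0.048 CPM), Rimbp2 (1.26 ± 0.20 and 0.718 ± 0.170 CPM) and Hormad2 (0.676 ± 0.173 and 0.26 ± 0.141 CPM), which did not pass either. On simulated counts for this contrast, over 16073 genes with 200 changed, 20.9% of genes changed 1.5-fold and 67.2% of those changed 2-fold were called. Most differences of 1.5-fold or less were therefore not detectable under the settings of the simulation. Each gene was drawn independently there, so these shares need not hold where genes vary together. With fewer genes changed than in the simulation, the adjustment is stricter and larger differences can be missed too. Ttn, 1.88-fold higher in males, did not pass. The count of autosomal calls was 7 with 1 surrogate variable, 18 with the foregut list as a covariate and 3 with the length trend as a covariate, the last 2 chosen after seeing the data.

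Genes of the contractile apparatus had higher values in males, but unevenly. Of 25 sarcomere genes, 23 were higher in males, with a median log2 fold change of 0.23 and an adjusted p of 8.48e-06 by the set test with a preset correlation. With an estimated correlation the adjusted p was 0.725. Of the 34 other ways of dividing the 8 libraries into 4 and 4, 17 also called the list with the preset correlation. In the list's mean log2 CPM relative to all libraries, Male replicates 1 and 3 (-0.006 and -0.096) lay below Female replicate 3 (-0.0006). Male replicates 2 and 4 (0.39 and 0.14) lay above all females. None of the 25 passed over all genes, and adjusted over the list alone 1 was called, Ttn, with a log2 fold change of 0.91 ± 0.21 (SE). The members with the most counts did not pass: cardiac alpha-actin Actc1 (11670 ± 1195 CPM in females and 11430 ± 310 CPM in males, SD, n = 4 each) and the atrial light chain Myl7 (6301 ± 1347 and 7409 ± 3010 CPM). Male replicate 2 had the highest mean of the list, 0.39 above the mean of all libraries in log2 CPM, and without it the median was 0.075 (adjusted p = 0.00483); without Female replicate 4 it was 0.14. Over all alternatives the adjusted p of the list ran from 8.45e-08 to 0.725. Cardiac transcription factors split evenly, 10 of 20 higher and 10 lower in males (adjusted p = 0.964; median 0.0057, while the test pointed down), with Nkx2-5 at 495 ± 58.9 and 519 ± 77.9 CPM and the muscle methyltransferase Smyd1 at 507 ± 49.1 and 504 ± 39.6 CPM in females and males. Of 16 atrial and sinus venosus genes, 11 were higher in males (adjusted p = 0.178); the natriuretic peptide Nppa stood at 532 ± 68.5 and 649 ± 87.1 CPM, and Myl1 at 381 ± 46.3 and 424 ± 32.0 CPM. This list passed without Female replicate 4 (adjusted p = 0.0474, the lowest of alternatives that ran up to 0.867). Of 18 genes of the ventricle and its trabeculae, 11 were higher in males (adjusted p = 0.589), with the ventricular light chain Myl2 at 2441 ± 195 and 2789 ± 463 CPM and Cited1 at 159 ± 9.53 and 188 ± 39.1 CPM. Of 20 genes of endocardium and endothelium, 12 were lower in males (adjusted p = 0.694), with Eng, a TGF-beta co-receptor, at 185 ± 24.7 and 214 ± 14.6 CPM and Plvap at 172 ± 5.86 and 179 ± 13.4 CPM.

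Markers of tissue next to the heart varied from library to library. Of 15 genes of foregut and pharyngeal epithelium, 14 had lower values in males, with a median log2 fold change of -0.73 and an adjusted p of 0.000705 by the set test with a preset correlation; with an estimated correlation the adjusted p was 0.743. None was called over all genes or over the list alone. The preset correlation also called the list in 22 of the 34 other ways of dividing the 8 libraries into 4 and 4. The members with the most counts were Krt18, a keratin that heart tissue also holds (124 ± 31.3 CPM in females and 118 ± 53.2 CPM in males, SD, n = 4 each), and Hhex (10.1 ± 3.12 and 8.16 ± 0.29 CPM). The mean of the list, in log2 CPM relative to all libraries, was 1.80 in Female replicate 1, 1.34 in Male replicate 2 and 0.58 in Female replicate 3, and between -1.18 and -0.33 in the other 5 libraries. Female replicate 1 and Male replicate 2 also had the highest means of the hepatic list, 2.10 and 1.17. Of the 15 foregut genes, 2 are also on another list, and 4 had at least 1 CPM in every library. Without Female replicate 1 the foregut median was 0.12 (adjusted p = 0.282), without Male replicate 2 it was -1.70, and without Male replicates 1 and 3 in turn it was -0.48 each time (adjusted p = 0.0232 and 0.0609), in a range of adjusted p over all alternatives from 2.63e-12 to 0.965.

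Further lists passed only with the preset correlation. Of 21 genes of cholesterol synthesis, 20 had lower values in males (median log2 fold change -0.10, adjusted p = 0.00694); Hmgcs1, which makes the precursor of mevalonate, stood at 164 ± 19.3 CPM in females and 141 ± 13.7 CPM in males (SD, n = 4 each). With an estimated correlation the adjusted p was 0.732. Of 20 targets of Notch, Bmp and Wnt signalling, 14 were lower in males (median -0.12, adjusted p = 0.0135, and adjusted p = 0.725 with an estimated correlation), with Id2 at 247 ± 41.0 and 220 ± 7.36 CPM and Smad6 at 142 ± 19 and 134 ± 33.8 CPM. Of 25 cell cycle genes, 19 were lower in males (median -0.12, adjusted p = 0.0249, and adjusted p = 0.743 with an estimated correlation). Cyclin Ccnd2 stood at 900 ± 96.5 and 1139 ± 509 CPM, with a log2 fold change of 0.34 that was -0.023 without Male replicate 2. Top2a stood at 315 ± 19 and 297 ± 19.1 CPM. Of 9 cardiac neural crest genes, 7 were lower in males (median -0.17, adjusted p = 0.0336, and adjusted p = 0.712 with an estimated correlation), with Ednra at 46.1 ± 4.56 and 43.7 ± 7.54 CPM and Ets1 at 40.9 ± 5.25 and 36.3 ± 6.99 CPM. All 8 macrophage and platelet genes were higher in males (median 0.28, adjusted p = 0.0329, and adjusted p = 0.512 with an estimated correlation), with Itga2b at 21.4 ± 2.86 and 25.3 ± 5.50 CPM and the platelet chemokine Pf4 at 3.46 ± 1.43 and 5.47 ± 2.02 CPM. No member of these 5 lists was called over all genes or over the list alone. Each of these calls was lost without some of the libraries. The cholesterol call ended without Female replicate 2 (adjusted p = 0.121, median -0.085) or Male replicate 1 (0.0632, median -0.087). The signalling call ended without Male replicate 2 (0.147, median -0.0875). The cell cycle call ended without Female replicate 2 (0.0559), Female replicate 4 (0.0584, median -0.07), Male replicate 2 (0.179, median -0.04) or Male replicate 4 (0.0558). The macrophage call ended without Female replicates 2 (0.0579) or 4 (0.0584) or Male replicates 1 (0.0621), 3 (0.217) or 4 (0.0558). Its median with each library left out stayed between 0.22 and 0.38. The neural crest call ended without Female replicates 2 (0.0594) or 4 (0.0804, median -0.09) or Male replicates 1 (0.179, median -0.07), 3 (0.0609, median -0.10) or 4 (0.0913, median 0.0015), and its median was -0.08 without Male replicate 2. The highest adjusted p over all alternatives was between 0.512 and 0.743 for these 5 lists. Of 32 lists, 8 passed with the preset correlation and 1, the escape list, with an estimated correlation or with fry; 24 of the 35 ways of dividing the 8 libraries into 4 and 4 gave at least 8 lists.

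**Figure D4:**
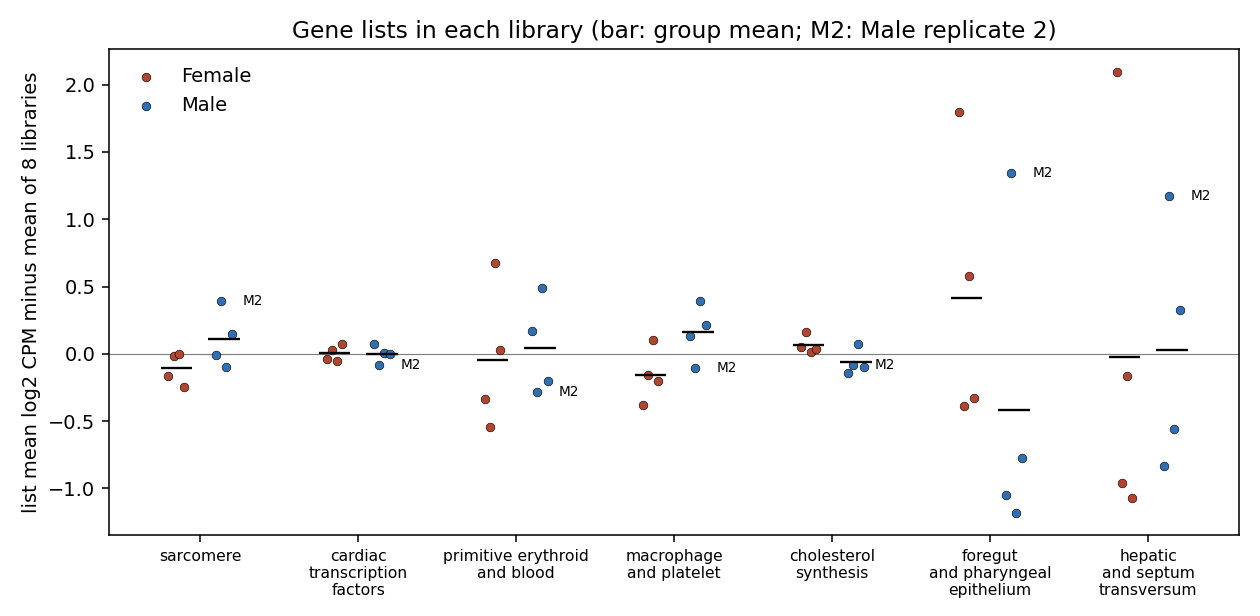
Mean log2 CPM of 7 gene lists in each library, relative to the mean of all 8 libraries; red points are female and blue points male libraries, bars are group means, and M2 marks Male replicate 2. The foregut list lies at 1.80 in Female replicate 1 and 1.34 in Male replicate 2, and the cardiac transcription factors lie between -0.09 and 0.08.

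Blood content overlapped between the sexes. Erythroid genes took 0.758% ± 0.347 of counts in females and 0.802% ± 0.187 in males (SD, n = 4 each, exact permutation p = 0.83). The embryonic globins Hbb-y (2395 ± 1168 and 2523 ± 697 CPM) and Hba-x (2318 ± 1092 and 2460 ± 344 CPM) varied more within than between the sexes, and of 19 erythroid genes 11 were higher in males (adjusted p = 0.635). Without Female replicate 3, the library with the largest erythroid share (1.26%), the erythroid list was higher in males by the set test with a preset correlation (median 0.42, adjusted p = 3.63e-05, the lowest of alternatives that ran up to 0.979). With an estimated correlation over all libraries the adjusted p of the list was 0.979. Of the 34 other ways of dividing the 8 libraries into 4 and 4, 20 also called it with the preset correlation.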

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

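Tests of sequencing depth, of foregut and hepatic tissue in Male replicate 2 and of carried-over tissue in the foregut list were chosen after the result was seen. The others were set down before their own result. Of these, the tests with the foregut or length covariate use fits that were chosen after seeing the data.

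Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave 6 or more called genes. The highest of the other splits gave 0. The 6 genes are Xist and genes of chromosome Y, and the groups were set by genotyping Sry. The outcome follows from that grouping, so it checks the labels and cannot decide whether sex alters other genes. For the number of gene lists chance cannot be excluded, since 24 of the 35 splits gave 8 or more lists. The highest other split gave 12. The escape list passed with the preset correlation in 13 of the 34 other splits. Splits with unequal numbers of females on their sides keep part of the sex difference, so these calls do not measure chance for this list. Its mean, Xist included, lay between 0.35 and 0.50 in female libraries and between -0.46 and -0.38 in male libraries. Without Xist it passed with an estimated correlation (adjusted p = 0.0208) and with fry (adjusted p = 0.00613). For autosomal genes and for chromosome sets the real count was 0, which all 35 splits reach; the highest of the other splits gave 0 autosomal genes and 2 chromosomes.

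In 194 groups of 4 libraries checked, 9 values lay far from the other 3 libraries of their sex, close to the 1 in 20 that chance flags. Male replicate 2 held 5 of them. Its mean of the second heart field and outflow tract list was 0.43, against -0.32 to -0.22 in the other male libraries, and its foregut mean was 1.34, against -1.18 to -0.77. It had 2.01 CPM of Ftx (4.37 to 4.62 in the other males), 1.57 CPM of Car5b (0.663 to 0.782) and 1895 CPM of Ccnd2 (831 to 990.2). Male replicate 3 had 112 CPM of Myh7b (142 to 145). Female replicate 3 had 3941 CPM of Hba-x (1574 to 1922) and 287 CPM of Top2a (324 to 326). Female replicate 4 had 757 CPM of Ccnd2 (930.0 to 958).

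Male replicate 2 stands apart from the other libraries, with a standard deviation across genes of its deviation from the other males of 0.705, against 0.269 to 0.481 in the other 7 libraries. Its depth ranked 3 of 8, which argues against depth, and smooth trends on transcript length and GC content explained 7.72% and 1.75% of the variance of that deviation, too little to account for it. Foregut and hepatic tissue is argued against as the whole cause, since Female replicate 1, with higher foregut and hepatic means, lay 0.301 times as far out on the first component. The library also had the highest means of replication-dependent histones (1.25), ribosomal proteins (0.59) and the somite and skeletal muscle list (0.73, against 0.28 in Female replicate 1). Other tissue, handling and embryo stage were not tested, and no biological explanation was tested.

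The sarcomere list had higher values in males by the set test with a preset correlation. Less tissue from outside the heart in male libraries, as far as the foregut list measures it, is argued against by the size of the median. With the foregut mean as a covariate the median was 0.27 (adjusted p = 0.000139), beside 0.23 without it. Male replicate 2 may give much of the size, since without it the median was 0.075, though the set test still passed (adjusted p = 0.00483). Both adjusted p-values used the preset correlation, which also called the list in 17 of the 34 other splits. They therefore carry little weight for or against a cause. Correlation between the genes of the list may give the small p, since with an estimated correlation the unadjusted p was 0.0948. Sex stays open and untested apart from these.

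The foregut list had lower values in males by the same test. Tissue carried over to a different extent in each library may account for it, since the sexes overlapped in the mean of the list (exact permutation p = 0.314), and so may correlation between its genes (unadjusted p = 0.256 with an estimated correlation). With the length trend of each library as a covariate the median was -0.62 and the adjusted p 0.0824, beside -0.73 and 0.000705 without it. The medians with each library left out had a standard deviation of 0.529, so a part for RNA quality cannot be told apart from chance movement. Sex stays open as well.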

How the results depend on the processing

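Fits without Female replicate 1 and Male replicate 2, with the foregut or length covariate, or on the genes of the normalized table were chosen after seeing the data. Xist, Eif2s3y, Ddx3y, Kdm5d and Uty were called in the same direction in all 25 alternatives, and Gm29650 in 24. The total of 6 genes stayed within 1.5 times except with 1 surrogate variable (19), the foregut covariate (27), the length covariate (11) and without chromosomes X and Y (0, by construction). Autosomal calls became 7, 18 and 3 with those 3 covariates. ENSMUSG00000051412, on GL456233.1, a sequence outside the named chromosomes, was counted as neither autosomal nor sex-linked and was named after its values were seen. It was called lower in males with DESeq2 (log2 fold change -0.51, adjusted p = 0.00145) and with 1 surrogate variable (-0.50, adjusted p = 0.00161). X-linked calls became 2 with DESeq2, with no filter, with a filter at 1 CPM and with the length covariate, 5 with the surrogate variable, 3 with the foregut covariate, and 1 to 2 with each library left out. The 8 lists became 4 with the 1 CPM filter, 1 with an estimated correlation, 1 with fry, and 4 to 12 with each library left out (4 without Female replicate 2). Chromosome sets became 1 with no filter (chromosome Y, which then had enough genes) and 0 to 1 with each library left out. Gm4017 on chromosome Y, which lies within Ddx3y and was named after its values were seen, had an adjusted p of 0.285 and passed with DESeq2 (9.2e-08), limma-voom (0.00634), no filter (0.00781), the erythroid (0.0247), foregut (0.00671) and length (0.00666) covariates, 1 surrogate variable (2.86e-05) and the normalized signal (0.0056), in a range of alternatives up to 0.9998. The cause of these moves was not tested.

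The labels give both sexes replicate numbers 1 to 4. With the replicate block 5 genes were called, 1 of them X-linked. Deviations of same-numbered female and male libraries correlated at -0.42, -0.08, -0.33 and -0.01, none of them positive. With Male replicate 2 far from the other libraries, these values cannot decide whether the numbers mark a shared litter or day. Permutation tests with a library left out cannot go below 0.0571, and those within numbers cannot pass the threshold either.

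Values that changed sign were not called in the fit reported, apart from 2 lists. With each library left out, the median of the foregut list ran from -1.70 to 0.12 and that of the neural crest list from -0.20 to 0.0015. For transcription factors it ran from -0.039 to 0.044, and was -0.016 with library size alone, -0.017 with no filter, -0.0003 with the replicate block, -0.010 with the erythroid, -0.064 with the foregut and -0.033 with the length covariate. The ventricle list ran from -0.015 to 0.094 (-0.020 and -0.0018 with the foregut and length covariates), the endothelium list from -0.065 to 0.053 (0.030 with the surrogate variable), and the erythroid list from -0.14 to 0.42 (-0.084 with the foregut covariate). Without Female replicate 1 and Male replicate 2 together, the endothelium median was 0.018, the atrial median -0.036, and log2 fold changes were 0.047 for Shroom4, 0.10 for 1810030O07Rik, 0.084 for Ftx, -0.090 for Myl7, -0.032 for Nkx2-5, 0.014 for Ednra and -0.013 for Hba-x. With each library left out, Shroom4 ran from -0.092 to 0.060, 1810030O07Rik from -0.075 to 0.099, Eif1ax from -0.15 to 0.025, Actc1 from -0.086 to 0.029, Myl7 from -0.078 to 0.39, Smyd1 from -0.067 to 0.044, Nkx2-5 from -0.038 to 0.13, Ednra from -0.16 to 0.032, Hbb-y from -0.13 to 0.46, Hba-x from -0.061 to 0.47, Krt18 from -0.42 to 0.095, Ccnd2 from -0.023 to 0.46 and Smad6 from -0.18 to 0.080. With the surrogate variable Shroom4 was at 0.030, 1810030O07Rik at 0.034 and Smyd1 at 0.027. With the 1 CPM filter 1810030O07Rik was at 0.002 and Smyd1 at 0.0023, and Smyd1 was at 0.0006 with limma-voom and 0.0015 on the normalized signal. With the foregut and length covariates Eif1ax was at 0.048 and 0.0092 and Krt18 at 0.19 and 0.078; with the foregut covariate Hbb-y was at -0.019. Summed CPM, male minus female, ran from -0.862 to 1.2 for Kdm6a and Uty (-0.273 with library size alone), from -5.33 to 4.58 for Usp9x and Usp9y and from -9.94 to 0.67 for Kdm5c and Kdm5d. The erythroid share difference ran from -0.0447 to 0.212 percentage points.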

Other observations

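The test of the escape genes within the X set was set down before its result was seen; the values in the other paragraphs were picked afterwards.

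Genes of steroid hormone signalling did not pass as a set. Of 8 tested members, 3 were higher and 5 lower in males (adjusted p = 0.588 by the set test), with Hsd17b4 at 86.8 ± 8.15 CPM in females and 77.2 ± 12.2 CPM in males (SD, n = 4 each) and Hsd17b12 at 80.7 ± 4.04 and 74.7 ± 10.6 CPM. Lists of energy metabolism did not pass either. Of 38 nuclear genes of oxidative phosphorylation 23 were higher in males (adjusted p = 0.881), of 20 glycolytic genes 13 (adjusted p = 0.92), and of 20 genes of fatty acid oxidation 11 (adjusted p = 0.612). Of 20 hypoxia genes 15 were lower in males (adjusted p = 0.0661, and adjusted p = 0.783 with an estimated correlation), and of 25 extracellular matrix genes 18 were higher (adjusted p = 0.0627, and adjusted p = 0.783 with an estimated correlation).

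The lower values of X-linked genes in males by the set test, which did not pass over 21 chromosomes (unadjusted p = 0.00639, adjusted p = 0.134), may come from the escape genes alone: without the 15 tested members of that list, 527 X-linked genes had a median log2 fold change of -0.02 and an unadjusted p of 0.115. That p does not show that the remaining genes were equal.

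Gm47283, annotated on chromosome Y at 90784738 to 90816464, had 260 ± 92.4 CPM in females and 206 ± 157 CPM in males (SD, n = 4 each), unlike the other Y-linked genes tested. Female libraries held 39399 counts of Gm47283 and 17 of Eif2s3y. These values argue against chromosome Y as the source of its female counts. How reads that map to several places were counted is not given in the sources used here, so its source in males is not known. Sry itself had 0 counts in all 8 libraries.

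With 1 surrogate variable the 7 autosomal calls were Fbn2, Ncam1, Myh7b, Hspg2, Dync1h1 and 1110002E22Rik, higher in males, and Inava, higher in females. Fbn2, a fibrillin of extracellular microfibrils, had a log2 fold change of 0.38 ± 0.06 (SE, adjusted p = 0.0086, edgeR) there and was also among the 18 calls with the foregut covariate, at 0.79 ± 0.12 (SE, adjusted p = 0.0345). All 18 of those calls were higher in males.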
